A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

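The study measured ribosome footprints and poly(A) mRNA in Saccharomyces cerevisiae SK1 grown in YEPD at 30 °C to an optical density of 0.6 and treated for 1 minute with 100 µM cycloheximide, per the labels. Footprints of 28 to 31 nt and mRNA fragments of 50 nt were selected by size, per the labels' protocols. Per the submitters' processing notes, the tools were CASAVA, bcl2fastq 2.17 and Bowtie2. The role of each tool, the genome build, the annotation and the counting rules are not given in the sources used here.

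The deposited values are RPKM (reads per kilobase, scaled to library depth), 1 column per library, and the labels name no unit. The unit was read from the values: for genes with few reads, each value times the gene length minus 60 nt is a multiple of 1 step per library. Of values up to 200 reads, 83.7% to 87.7% came out whole within 0.02 reads when lengths were taken from the R64 reference. The steps give 6.0 to 8.5 M reads per mRNA library and 8.7 to 13.11 M per footprint library, and this depth is inferred, not stated. At 5 RPKM, a gene of 1 kb then has 28 to 40 reads in an mRNA library and 41 to 62 in a footprint library. Counting error included, replicates of a group had a median absolute log2 difference of 0.1 to 0.132.

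The table holds 6159 gene IDs, of which 5637 matched the R64 reference gene table, used here for names, coding lengths and neighbouring genes only. The other 522 kept their IDs, and 188 genes were 0 in every library. All 12 libraries were grouped by genotype and library type from the titles and genotype labels.

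From the RPKM values, log2(RPKM + 1) was fitted with limma 3.58.1 (trended empirical Bayes) in R 4.3.3, separately for the 6 mRNA and the 6 footprint libraries. The 3 genotypes shared 1 estimate of the spread. Genes needed a mean of at least 5 RPKM over the libraries of the fit, and in both library types for translational efficiency. Translational efficiency was the interaction of genotype and library type over 12 libraries, that is, the footprint log2 fold change minus the mRNA log2 fold change. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, over 5198 genes in mRNA, 4830 in footprints and 4785 in translational efficiency. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

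Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Beside it stands the adjusted p with a correlation estimated from the data, with which no list passed in any comparison. With that setting camera also takes its degrees of freedom from the residuals, 3 in mRNA and footprints and 6 in translational efficiency. The adjusted p-values under these settings therefore differ by more than the correlation. The lists were Hsf1-dependent chaperones, general stress genes, cytosolic ribosomal proteins, ribosome biogenesis, translation initiation factors, translation elongation and termination factors, amino acid biosynthesis under Gcn4, glycolysis and fermentation, the nuclear-encoded respiratory chain and ATP synthase, the proteasome, genes with known upstream open reading frames, cyclins, histones, other DEAD-box helicases, ergosterol synthesis, cell wall and mannoprotein genes, the phosphate and iron regulons, meiotic and sporulation genes, haploid-specific and mating genes, and strain marker genes. A list of mitochondrially encoded genes had no member in the table, which left 21 lists. The name pattern behind the ribosomal protein list also took in RPP1, an RNase P subunit that is not a ribosomal protein. Left off, an alternative chosen after seeing the data, no call changed, and the list's median was -0.126 against -0.127 in Dbp1 against Ded1 mRNA. In total 11 list members were unmatched, and some genes, such as TIF1 and TIF2, belong to more than 1 list. Meiotic and mating genes stand for other cell states the cultures could hold.

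The genes named in the text follow a rule. It takes DED1 and DBP1 in every comparison, and the 8 largest increases and decreases in mRNA and in translational efficiency (4 each in footprints) among genes past the threshold with a mean of at least 10 RPKM in both library types and no overlap between the replicates of the 2 genotypes, leaving aside dubious or overlapping unnamed genes. Where none passed in a direction, it takes the 3 with the lowest p. For each list in mRNA and translational efficiency it takes up to 4 members past the threshold, or else the 2 with the lowest p. The text prints fewer. The rule, the tests, the lists and the alternatives, except where said otherwise, were fixed before the data were examined. The test planned for raw counts was not needed, since the values are RPKM.

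Same-numbered mRNA and footprint libraries of 1 genotype deviated from their group means together, with correlations of 0.417 in 2xDbp1, 0.657 in Dbp1 and 0.533 in Ded1, each over the bound of 0.1. They were therefore treated as pairs in an alternative fit of translational efficiency, whose standard errors leave out deviations that the paired libraries share. The pairing comes from the numbers in the titles and this check.

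The fits were tested on simulated data with the genes' real means. The spread of each gene was limma's empirical Bayes estimate, the same for every genotype. In each fit, 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. For Dbp1 against Ded1, calls recovered 68.7% of 1.5-fold, 97% of 2-fold and 98.5% of 4-fold changes in mRNA over 5198 genes, with 2.6% of calls false. For footprints over 4830 genes the shares were 85.1%, 95.5% and 100%, with 7.4% false, and for translational efficiency over 4785 genes 41.8%, 82.1% and 98.5%, with 4.8% false. In 2xDbp1 against Ded1, left unchanged in the simulation, 4 genes were called in mRNA, 1 in footprints and 2 in translational efficiency. The simulated noise was independent between genes and libraries, unlike that of the real libraries, so these shares may not hold for the real comparisons.

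The alternatives were a pseudocount of 0.1 or 5, no filter or a minimum mean of 20 RPKM, rescaling of the libraries to a common median ratio, the replicate number as a term, pairs of mRNA and footprint libraries, library weights by type, the 2 compared genotypes alone, an estimated inter-gene correlation, and each library left out in turn. Correlations between the comparisons against Ded1 were set beside 100 simulations of unchanged genotypes with shared controls. A move of 0.05 in such a correlation was counted as a change, a bound chosen here.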

Results

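Ribosome footprints and poly(A) mRNA were sequenced from exponentially growing mitotic budding yeast of the SK1 strain, in 12 libraries. DED1 and DBP1 are paralogs that encode DEAD-box RNA helicases acting in translation initiation. In the 3 genotypes, the DED1 regulatory regions drove DED1 (Ded1), DBP1 (Dbp1), or 4 copies of DBP1 (2xDbp1). Each genotype had 2 mRNA and 2 footprint libraries, which makes 6 groups of n = 2. The series' stated purpose for the extra copies was to bring DBP1 to the level of the other helicase and so to test how specific each helicase is. The mRNA libraries held 6.0 to 8.5 M reads and the footprint libraries 8.7 to 13.11 M, as recovered from the steps between deposited values. The labels do not say whether same-genotype libraries came from separate cultures, so every single-gene p-value measures the spread between these samples only. A list's camera p-value sets its genes against all others, taken as nearly independent at the preset correlation. It is therefore no measure of agreement between replicates.

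The helicase genes followed the genotype labels in all 12 libraries. DED1 mRNA was 62.2 ± 1.1 RPKM (SD, n = 2) in Ded1, 2.78 ± 0.0545 in Dbp1 and 1.84 ± 0.0373 in 2xDbp1. DED1 footprints were 719.7 ± 14.1 RPKM in Ded1, 3.74 ± 1.09 in Dbp1 and 2.82 ± 0.578 in 2xDbp1. DBP1 mRNA was 4.69 ± 0.604 RPKM in Ded1, 102.4 ± 2.93 in Dbp1 and 154.4 ± 1.68 in 2xDbp1, and DBP1 footprints were 7.75 ± 0.553, 572 ± 1.81 and 932 ± 15.1 RPKM. Relative to DED1 footprints in Ded1, DBP1 footprints were 0.795 times as many in Dbp1 and 1.29 times as many in 2xDbp1. The corresponding mRNA ratios were 1.64 and 2.48. In 2xDbp1, DBP1 was 1.51 times its Dbp1 level in mRNA and 1.63 times in footprints, with no overlap between the libraries. Neither difference passed over all genes (limma, adjusted p = 0.303 and 0.113). Libraries of these genotypes did not overlap for 39.5% of all genes tested in mRNA and 42.2% in footprints. Footprints per mRNA were 11.6 ± 0.43 for DED1 in Ded1, 5.59 ± 0.18 for DBP1 in Dbp1 and 6.04 ± 0.16 for DBP1 in 2xDbp1. Paralogs can share reads, so the lowest values of each gene are uncertain.

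**Figure D1:**
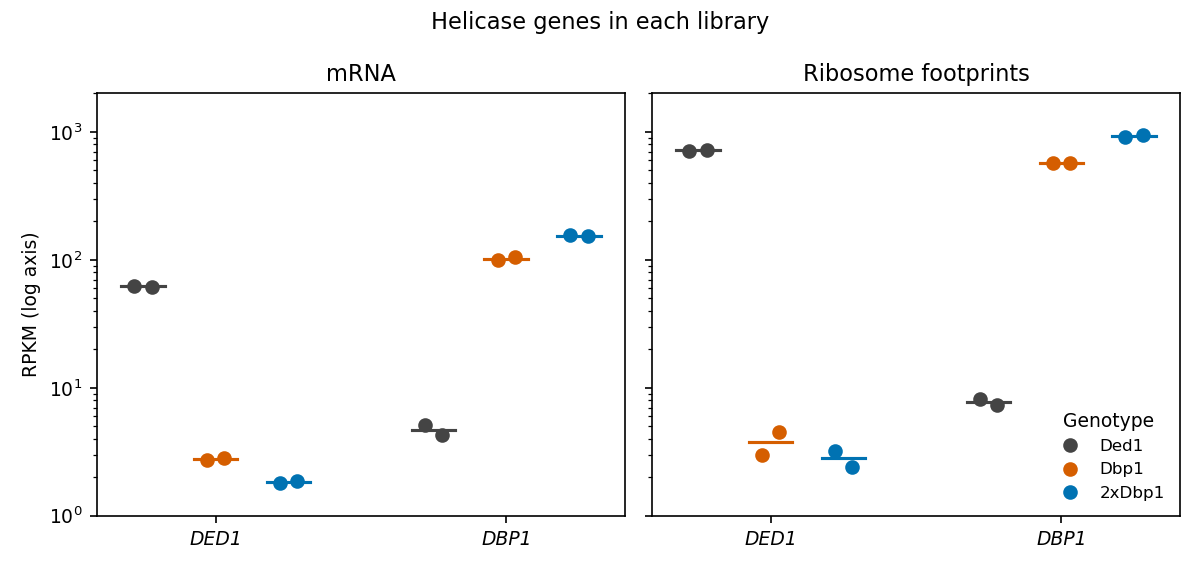
RPKM of DED1 and DBP1 on a log axis, in mRNA libraries (left) and ribosome footprint libraries (right); points are the 2 libraries of a genotype and lines their means. DBP1 footprints in Dbp1 (572) and 2xDbp1 (932) lie on either side of DED1 footprints in Ded1 (719.7).

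Dbp1 against Ded1 asks what differs when DBP1 takes the place of DED1 at its own regulatory regions. General stress genes, the targets of the transcription factors Msn2 and Msn4, were higher in Dbp1 mRNA. Of 30 measured members 15 rose, 0 fell and 15 did not pass, and 27 rose adjusted over the list alone. HSP12, a membrane-associated small heat shock protein, rose from 41.0 ± 33.2 to 509.2 ± 233 RPKM (log2 fold change +3.79, SE 0.553, adjusted p = 0.0336). HSP12 did not pass without Dbp1 replicate 1 (adjusted p = 0.127), Ded1 replicate 1 (log2 fold change +2.88, adjusted p = 0.0951), 2xDbp1 replicate 1 (adjusted p = 0.0868) or 2xDbp1 replicate 2 (adjusted p = 0.0859). DCS2 rose by 1.99 on the log2 scale, GPH1 (glycogen phosphorylase) by 1.93, PHM8 by 1.48, PGM2 (phosphoglucomutase) by 1.41 and MSC1 by 1.40. The list's median was +1.18, which ranked it above other genes (camera, adjusted p = 4.07e-21, and adjusted p = 0.286 with an estimated correlation). Outside that list, RTC3 (+1.93, adjusted p = 0.0041), YOL153C (+1.64), FAA1, a long-chain acyl-CoA synthetase (+1.51), and STF1 (+1.37) also rose. The glycolytic genes TDH1 (+1.71) and ENO1 (+0.84) rose while 15 of the 17 members of the glycolysis and fermentation list did not pass, and the list's test did not pass (median +0.05, adjusted p = 0.451). With no filter on low values, FAA1 (adjusted p = 0.062), TDH1 (adjusted p = 0.0646) and ENO1 (adjusted p = 0.0581) did not pass.

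Genes of sulfur amino acid synthesis were 4 of the 11 transcripts, DED1 aside, that fell in Dbp1. MET2, homoserine acetyltransferase, fell from 39.0 ± 0.425 to 16.6 ± 0.284 RPKM (log2 fold change -1.19, SE 0.12, adjusted p = 0.0104). MET2 did not pass without Dbp1 replicate 1 (adjusted p = 0.0525), Ded1 replicate 1 (adjusted p = 0.0988) or Ded1 replicate 2 (adjusted p = 0.0607). MET17 fell by 1.09 on the log2 scale, MHT1 by 0.99 and MET14 by 0.62. The aquaporin gene AQY2 (-1.29), the cell wall mannoprotein gene CWP2 (-1.02), the hexose transporter gene HXT2 (-0.64) and AAH1 (-0.61) fell as well. DBP2 (-0.57) was the 1 of 14 other DEAD-box helicases that changed, and the list's test did not pass (median -0.01, adjusted p = 0.179). PHM6 (-1.92) was the 1 of 10 phosphate regulon members that changed (list median -0.12, adjusted p = 0.199). With no filter, CWP2 (adjusted p = 0.052), AAH1 and PHM6 (adjusted p = 0.0603 for both) did not pass, nor did PHM6 with a pseudocount of 5 (adjusted p = 0.0739).

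In all, 79 of 5198 genes changed in mRNA between Dbp1 and Ded1, 67 higher and 12 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Without DED1 and DBP1 there were 66 and 11, of which 28 and 5 changed at least 2-fold. Unadjusted p was under 0.05 for 1016 genes, against 260 by chance. The count depended on the libraries in the fit. It was 8 with the 2 compared genotypes alone and 55 with no filter on low values. Leaving out a library lowered it, except for Dbp1 replicate 2, without which it rose. It fell also without a 2xDbp1 library, which is not compared here but shares in the estimate of the spread. A fall without a Dbp1 or Ded1 library therefore need not come from that library's values. Of the 26 named genes that passed, helicases included, some calls were lost without each library. None of the named genes changed direction.

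In mRNA 8 lists passed as wholes, 2 higher and 6 lower, and apart from general stress genes they moved by little. Ribosome biogenesis genes were lower in all 61 measured members (median -0.26, 0 past the threshold, 11 lower adjusted over the list alone, adjusted p = 3.49e-21, and adjusted p = 0.369 with an estimated correlation). DBP8 (-0.51, adjusted p = 0.0517) and NMD3 (-0.42, adjusted p = 0.0851) had the lowest p among them. Genes of the respiratory chain and ATP synthase were higher in all 33 members (median +0.36, 0 past the threshold, 18 higher adjusted over the list alone, adjusted p = 2.44e-11, and adjusted p = 0.58 with an estimated correlation), with the lowest p for SDH4 (+0.88, adjusted p = 0.0593) and QCR6 (+0.49, adjusted p = 0.0737). Their mean log2(RPKM + 1) was 10.173 and 9.816 in the Dbp1 libraries and 9.511 and 9.667 in the Ded1 libraries, and its change fell from 0.406 to 0.227 without Dbp1 replicate 1. Cytosolic ribosomal proteins were lower (median -0.13 over 127 genes, RPP1, an RNase P subunit, among them, adjusted p = 1.27e-15, and adjusted p = 0.369 with an estimated correlation). Translation initiation factors had a median of -0.13 over 25 genes (adjusted p = 2.1e-05, and adjusted p = 0.369 with an estimated correlation). Elongation and termination factors had a median of -0.11 over 12 genes (adjusted p = 0.0141, and adjusted p = 0.542 with an estimated correlation). Cell wall and mannoprotein genes had a median of -0.12 over 25 genes (adjusted p = 0.0141, and adjusted p = 0.621 with an estimated correlation), and ergosterol synthesis genes one of -0.06 over 22 genes (adjusted p = 0.0404, and adjusted p = 0.881 with an estimated correlation). Apart from CWP2, none of the members of these lists passed over all genes. Among Hsf1-dependent chaperones HSP42 (+1.17) and HSP78 (+0.85) rose, but the list's median was +0.03 (adjusted p = 0.357), and after rescaling the libraries it was -0.004 and HSP78 no longer passed (adjusted p = 0.0569, and 0.0616 with no filter).

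In footprints, general stress and ribosome biogenesis genes had more members past the threshold than in mRNA, a difference that was not tested. HSP12 footprints rose from 42.2 ± 32.6 to 397.0 ± 199 RPKM (log2 fold change +3.35, SE 0.554, adjusted p = 0.0321). HSP12 footprints did not pass without Dbp1 replicate 1 (adjusted p = 0.117), Ded1 replicate 1 (log2 fold change +2.49, adjusted p = 0.0934), 2xDbp1 replicate 1 (adjusted p = 0.0766) or 2xDbp1 replicate 2 (adjusted p = 0.0755). RTN2, a reticulon, rose by 2.86 on the log2 scale (adjusted p = 0.00556), YRO2 by 2.35 and YGP1, a cell wall-related glycoprotein, by 2.32. MHT1 (-1.47), MET17 (-1.35), MET5, a sulfite reductase subunit (-1.32), and MET2 (-1.24) fell. With no filter, HSP12 and YRO2 (adjusted p = 0.0507 for both), YGP1 (adjusted p = 0.0566) and MET5 (adjusted p = 0.055) footprints did not pass. Of 28 general stress genes 23 rose and 0 fell, 27 adjusted over the list alone (median +1.58, adjusted p = 6.27e-27, and adjusted p = 0.3 with an estimated correlation). Of 61 ribosome biogenesis genes 3 fell, 54 adjusted over the list alone (median -0.34, adjusted p = 7.87e-24, and adjusted p = 0.486 with an estimated correlation). Respiratory chain and ATP synthase genes had a median of +0.37 (0 past the threshold, 20 adjusted over the list alone, adjusted p = 1.06e-11, and adjusted p = 0.641 with an estimated correlation), with means of 10.248 and 9.868 in the Dbp1 libraries and 9.593 and 9.714 in the Ded1 libraries, and the change of the mean fell from 0.404 to 0.214 without Dbp1 replicate 1.

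Footprints changed for 160 of 4830 genes, 117 higher and 43 lower, with 1133 at an unadjusted p under 0.05 against 242 by chance. Without the helicases, 116 rose and 42 fell, of which 50 and 9 changed at least 2-fold. The count was 42 without Dbp1 replicate 1, 245 without Dbp1 replicate 2, 22 without Ded1 replicate 1, 62 without Ded1 replicate 2, 43 without 2xDbp1 replicate 1 and 44 without 2xDbp1 replicate 2. It was 45 with the 2 compared genotypes alone and 96 with no filter on low values. The 10 genes named for footprints, helicases included, kept 7, 9, 6, 7, 5 and 5 calls in the order of those 6 libraries.

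Translational efficiency, the footprint change beyond the mRNA change, passed in Dbp1 against Ded1 for DED1 (-3.20) and DBP1 (+1.85) alone among 4785 genes. Both values rest on the lowest levels of each gene, which are uncertain because paralogs can share reads, so their size is uncertain too. The DED1 regulatory regions drove DBP1 in Dbp1 and DED1 in Ded1, so the genotypes were built to differ at both genes. DBP1 footprints per mRNA were 1.66 ± 0.096 in Ded1 and 5.59 ± 0.18 in Dbp1. Both calls may come from the strain design alone and do not show an effect of the helicases on translation. RTN2 had the next largest named change, +1.65 with an SE of 0.372 (adjusted p = 1). With mRNA and footprint libraries of the same number taken as pairs, the RTN2 value passed as well (SE 0.123, adjusted p = 0.00134), for a count of 3. Unadjusted p was under 0.05 for 151 genes in limma's unpaired fit and 354 in the paired fit, against 239 by chance. In every comparison, the unpaired fit counts deviations that paired libraries share as error. Its few calls therefore do not show that translational efficiency was unchanged. General stress genes stood above other genes (median +0.30 over 28 genes, adjusted p = 1.62e-07, and adjusted p = 0.667 with an estimated correlation), as did cytosolic ribosomal proteins (median +0.06 over 125 genes, adjusted p = 5.03e-06, and adjusted p = 0.866 with an estimated correlation). Ribosomal protein genes are short, and translational efficiency changes in this comparison had a Spearman correlation of -0.184 with coding length across 4742 genes, which are not independent replicates.

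**Figure D2:**
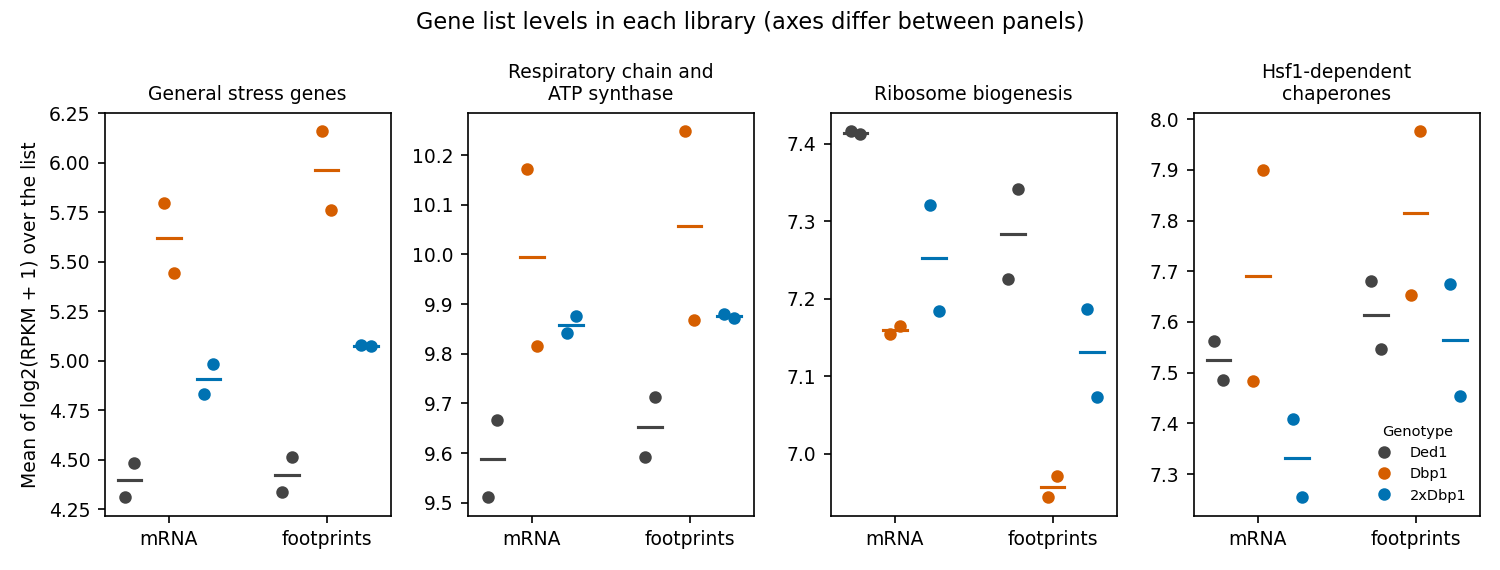
Mean of log2(RPKM + 1) over the members of 4 gene lists, in mRNA and footprint libraries; points are the 2 libraries of a genotype, lines their means, and axes differ between panels. General stress genes in mRNA averaged 4.40 in Ded1, 5.62 in Dbp1 and 4.91 in 2xDbp1, with no overlap between genotypes. Such separation is common: of all single genes tested in mRNA, 51.6% did not overlap in Dbp1 against Ded1. The share was 52.2% in 2xDbp1 against Ded1 and 39.5% in 2xDbp1 against Dbp1.

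2xDbp1 against Ded1 asks the same question at the higher DBP1 level. Beyond the helicases, MBB1 rose from 26.9 ± 0.0955 to 52.3 ± 1.91 RPKM in mRNA (log2 fold change +0.93, SE 0.09, adjusted p = 0.0167). TRP1, a tryptophan synthesis gene used as a strain marker, fell from 76.9 ± 9.22 to 6.11 ± 0.58 RPKM (log2 fold change -3.45, SE 0.125, adjusted p = 2.17e-05). MET2 footprints fell by 1.06 on the log2 scale (SE 0.106, adjusted p = 0.0423). Sulfur amino acid genes in mRNA had negative values that did not pass, MET17 at -1.13 (adjusted p = 0.0772), MET2 at -0.94 (adjusted p = 0.051) and MET6 at -0.98 (adjusted p = 0.178). Footprint values of GLK1, glucokinase (+1.02, adjusted p = 0.0882), YOL153C (+1.08) and GSY2, glycogen synthase (+0.83) did not pass either.

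General stress genes in 2xDbp1 had a median of +0.47 in mRNA (0 of 30 past the threshold, 9 higher adjusted over the list alone, adjusted p = 3.42e-07, and adjusted p = 0.615 with an estimated correlation). In footprints it was +0.69 (0 of 28, 20 adjusted over the list alone, adjusted p = 7.22e-17, and adjusted p = 0.373 with an estimated correlation). Ribosome biogenesis genes had medians of -0.17 in mRNA (adjusted p = 1.24e-11, and adjusted p = 0.626 with an estimated correlation) and -0.15 in footprints (adjusted p = 6.2e-14, and adjusted p = 0.684 with an estimated correlation). Respiratory chain and ATP synthase genes had medians of +0.23 (adjusted p = 1.04e-06, and adjusted p = 0.741 with an estimated correlation) and +0.20 (adjusted p = 2.31e-06, and adjusted p = 0.684 with an estimated correlation). Hsf1-dependent chaperones were lower in mRNA (median -0.22 over 19 genes, adjusted p = 0.00063, and adjusted p = 0.741 with an estimated correlation), and phosphate regulon genes higher (median +0.42 over 10 genes, adjusted p = 0.0145, and adjusted p = 0.741 with an estimated correlation). The phosphate regulon mean was 5.551 and 5.143 in the Ded1 libraries and 5.871 and 5.703 in the 2xDbp1 libraries, and its change fell from 0.44 to 0.236 without Ded1 replicate 2. Without 2xDbp1 replicate 2, the change of the mean in mRNA shrank from -0.193 to -0.116 for Hsf1-dependent chaperones. For ribosome biogenesis genes it shrank from -0.162 to -0.094. In footprints the ribosome biogenesis change shrank from -0.152 to -0.095 without Ded1 replicate 2. None of the members of these 5 lists passed over all genes.

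In mRNA 4 of 5198 genes changed between 2xDbp1 and Ded1, DBP1, DED1, TRP1 and MBB1, with 785 at an unadjusted p under 0.05. The count was 27 without Dbp1 replicate 1 or 2, 26 with the 2 compared genotypes alone, 10 with a minimum mean of 20, and 8 (5 higher and 3 lower) after rescaling. MBB1 no longer passed without 2xDbp1 replicate 1 (adjusted p = 0.259) or 2 (adjusted p = 0.175), or without Ded1 replicate 1 (adjusted p = 0.145) or 2 (adjusted p = 0.179). In footprints 3 of 4830 genes changed, DBP1, DED1 and MET2, with 449 at an unadjusted p under 0.05. That count was 22 without Dbp1 replicate 1 or 2, 6 without Ded1 replicate 1, and 12 with the 2 compared genotypes alone. MET2 footprints no longer passed without 2xDbp1 replicate 1 (adjusted p = 0.402) or 2 (adjusted p = 0.46), without Ded1 replicate 1 (adjusted p = 0.18) or 2 (adjusted p = 0.252), or with no filter on low values (adjusted p = 0.0618).

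Translational efficiency passed in 2xDbp1 against Ded1 for DED1 (-3.09) and DBP1 (+1.96), 2 of 4785 genes. In limma's unpaired fit, 245 genes had an unadjusted p under 0.05. Here too both values rest on each gene's uncertain lowest levels, and both calls may come from the strain design alone. The paired fit called 4 genes, with 549 unadjusted. It added RTN2 (+1.09, SE 0.123, adjusted p = 0.0231, against 0.909 unpaired) and GSC2, a glucan synthase subunit chosen after its values were seen (+1.37, SE 0.148, adjusted p = 0.0231, against 0.973 unpaired). EAP1, which encodes a protein that binds the cap-binding factor (+0.66), IPT1 (-0.57) and RPL39 (-0.46) did not pass (adjusted p = 0.692 for each). General stress genes had a median of +0.19 (adjusted p = 0.0108, and adjusted p = 0.939 with an estimated correlation) and glycolysis and fermentation genes one of +0.11 (adjusted p = 0.0108, and adjusted p = 0.939 with an estimated correlation). Hsf1-dependent chaperones (median +0.18) passed in the paired fit (adjusted p = 0.00923, and adjusted p = 0.724 with an estimated correlation) but not in the unpaired fit (adjusted p = 0.0956). Known upstream open reading frames marked 12 measured genes, whose median was +0.06 in 2xDbp1 (adjusted p = 0.325) and +0.04 in Dbp1 (adjusted p = 0.663).

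2xDbp1 against Dbp1 compares strains with more and fewer DBP1 copies, which also differed at TRP1. TRP1 mRNA fell by 3.43 on the log2 scale (SE 0.125, adjusted p = 6.8e-05), the 1 change among 5198 genes, with 404 at an unadjusted p under 0.05. General stress genes were lower in 2xDbp1, with a median of -0.61 in mRNA (0 of 30 past the threshold, 19 lower adjusted over the list alone, adjusted p = 2.01e-21, and adjusted p = 0.273 with an estimated correlation). In footprints their median was -0.77 (0 of 28, 25 adjusted over the list alone, adjusted p = 4.58e-28, and adjusted p = 0.283 with an estimated correlation). Members with the lowest p in mRNA were GAD1, glutamate decarboxylase (-0.86, adjusted p = 0.205), and MSC1 (-0.94, adjusted p = 0.303). RTC3 footprints were lower without passing (-1.32, adjusted p = 0.113). In footprints limma called 0 of 4830 genes, with 438 at an unadjusted p under 0.05, and 1 without Ded1 replicate 1, without Ded1 replicate 2, or with the 2 compared genotypes alone. The mRNA count was 6 without Dbp1 replicate 1 and 2 with a pseudocount of 5.

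General stress, ribosome biogenesis and respiratory chain genes had opposite signs in 2xDbp1 against Dbp1 and in Dbp1 against Ded1. These comparisons share the Dbp1 libraries, so that opposite signs are favoured without any effect. Ribosome biogenesis genes had medians of +0.10 in mRNA (adjusted p = 1.87e-06, and adjusted p = 0.563 with an estimated correlation) and +0.17 in footprints (adjusted p = 3.66e-15, and adjusted p = 0.637 with an estimated correlation). In mRNA the change of their mean fell from 0.093 to 0.025 without 2xDbp1 replicate 1. Respiratory chain and ATP synthase genes had medians of -0.12 (adjusted p = 0.000394, and adjusted p = 0.675 with an estimated correlation) and -0.18 (adjusted p = 3.7e-07, and adjusted p = 0.637 with an estimated correlation). Hsf1-dependent chaperones were lower in mRNA (median -0.32, 5 lower adjusted over the list alone, adjusted p = 1.59e-08, and adjusted p = 0.563 with an estimated correlation), HSP78 at -0.91 and HSP42 at -0.87 without passing singly. Their mean log2(RPKM + 1) was 7.484 and 7.899 in the Dbp1 libraries and 7.408 and 7.254 in the 2xDbp1 libraries, so Dbp1 replicate 1 lay near 2xDbp1 and the Dbp1 replicates differed by more than the change. Amino acid synthesis genes under Gcn4 had a median of -0.34 in mRNA (adjusted p = 1.59e-08, and adjusted p = 0.563 with an estimated correlation), with ARO1 at -0.52. Their mean log2(RPKM + 1) was 7.63 and 8.07 in the 2xDbp1 libraries and 8.252 and 8.166 in the Dbp1 libraries, a gap between 2xDbp1 replicates as large as the change. Phosphate regulon genes had a median of +0.51 (2 higher adjusted over the list alone, adjusted p = 2.19e-06, and adjusted p = 0.563 with an estimated correlation) and proteasome genes one of -0.14 (adjusted p = 9.75e-06, and adjusted p = 0.644 with an estimated correlation). For phosphate regulon genes the means were 5.411 and 4.772 in the Dbp1 libraries and 5.871 and 5.703 in the 2xDbp1 libraries, a gap of 0.639 between Dbp1 replicates beside a change of 0.696. Glycolysis and fermentation genes had a median of -0.07 in mRNA (adjusted p = 0.0485, and adjusted p = 0.675 with an estimated correlation), which did not pass after rescaling (adjusted p = 0.0649). None of the members of these lists passed over all genes.

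Translational efficiency passed for 0 of 4785 genes between 2xDbp1 and Dbp1 in limma's unpaired and paired fits, with 172 and 422 at an unadjusted p under 0.05 against 239 by chance, and for 1 gene with no filter on low values. RPS11B (-0.36) and RPL39 (-0.38), ribosomal protein genes, and RRP5 (+0.44), a ribosome assembly gene, had the lowest p of their lists (adjusted p = 0.999 for each). Cytosolic ribosomal proteins had a median of -0.08 (adjusted p = 1.09e-09, and adjusted p = 0.973 with an estimated correlation), ribosome biogenesis genes one of +0.06 (adjusted p = 0.0244, and adjusted p = 0.986 with an estimated correlation) and glycolysis and fermentation genes one of +0.09 (adjusted p = 0.0244, and adjusted p = 0.973 with an estimated correlation). General stress genes (median -0.08) passed in the paired fit (adjusted p = 0.0293, and adjusted p = 0.743 with an estimated correlation) but not in the unpaired fit (adjusted p = 0.175). Coding length had a Spearman correlation of 0.365 with these changes across 4742 genes, and ribosomal protein genes are short.

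Further lists passed with small medians and few single genes. In Dbp1 against Ded1 footprints, where 10 lists passed, cytosolic ribosomal proteins (-0.08, adjusted p = 0.000113) and ergosterol genes (-0.12, adjusted p = 0.00221) were lower (adjusted p = 0.641 with an estimated correlation for each). Initiation factors (-0.14, adjusted p = 0.000117) and cyclins (-0.16, adjusted p = 0.0114) were lower too (adjusted p = 0.486 with an estimated correlation for each), as were cell wall genes (-0.12, adjusted p = 0.00586, and adjusted p = 0.399 with an estimated correlation). Other DEAD-box helicases were lower (-0.13, adjusted p = 0.042, and adjusted p = 0.641 with an estimated correlation) and Gcn4 targets higher (+0.18, adjusted p = 0.026, and adjusted p = 0.861 with an estimated correlation). The Gcn4 targets' mean log2(RPKM + 1) was 7.751 and 8.427 in the Ded1 libraries and 8.375 and 8.301 in the Dbp1 libraries, so Ded1 replicate 1 alone lay lower. Hsf1-dependent chaperones did not pass (median -0.01, mean +0.20, tested as higher, adjusted p = 0.0998).

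In 2xDbp1 against Ded1, 12 lists passed in mRNA. Proteasome genes (-0.11, adjusted p = 0.0047), Gcn4 targets (-0.11, adjusted p = 0.00676) and ergosterol genes (-0.06, adjusted p = 0.0346) were lower (adjusted p = 0.741 with an estimated correlation for each). Elongation and termination factors (-0.09, adjusted p = 0.00801) and initiation factors (-0.07, adjusted p = 0.00872) were lower (adjusted p = 0.626 with an estimated correlation for each), as were other DEAD-box helicases (-0.12, adjusted p = 0.00872, and adjusted p = 0.615 with an estimated correlation). In footprints 9 lists passed. Ergosterol genes (-0.11, adjusted p = 8.36e-05), cytosolic ribosomal proteins (-0.04, adjusted p = 0.00155) and other DEAD-box helicases (-0.07, adjusted p = 0.0479) were lower, and phosphate regulon genes (+0.36, adjusted p = 0.0011) and glycolysis genes (+0.10, adjusted p = 0.0479, and 0.0926 after rescaling) higher (adjusted p = 0.684 with an estimated correlation for each). Cell wall genes were lower (-0.07, adjusted p = 0.00445, and adjusted p = 0.373 with an estimated correlation).

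In 2xDbp1 against Dbp1, 12 lists passed in mRNA. Cytosolic ribosomal proteins (+0.11, adjusted p = 2.67e-18, and adjusted p = 0.549 with an estimated correlation), initiation factors (+0.08, adjusted p = 0.0275, and adjusted p = 0.563 with an estimated correlation) and cell wall genes (+0.06, adjusted p = 0.0309, and adjusted p = 0.636 with an estimated correlation) were higher. Strain marker genes, of which TRP1 alone passed singly, were lower (-0.34, adjusted p = 0.00873, and adjusted p = 0.563 with an estimated correlation). In footprints 9 lists passed. Gcn4 targets (-0.33, adjusted p = 1.3e-06), proteasome genes (-0.12, adjusted p = 1.61e-05) and Hsf1-dependent chaperones (-0.21, adjusted p = 2.96e-05) were lower, and initiation factors (+0.12, adjusted p = 2.96e-05), phosphate regulon genes (+0.52, adjusted p = 0.000565) and cyclins (+0.16, adjusted p = 0.00836) higher (adjusted p = 0.637 with an estimated correlation for each). Phosphate regulon means were 5.922 and 5.085 in the Dbp1 footprint libraries, a gap beyond the change, and 6.171 and 6.019 in 2xDbp1. Gcn4 target means were 7.791 and 8.242 in the 2xDbp1 footprint libraries, also a gap beyond the change. That change shrank from -0.322 to -0.096 without 2xDbp1 replicate 1.

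For 12 of the 60 lists that passed in mRNA or footprints, the list's mean in the libraries of the compared genotypes overlapped. In 2xDbp1 against Dbp1 these were respiratory chain and proteasome genes in both library types, Hsf1-dependent chaperones in footprints and glycolysis genes in mRNA. In 2xDbp1 against Ded1 they were Gcn4 targets and ergosterol genes in mRNA, and cytosolic ribosomal proteins and other DEAD-box helicases in footprints. In Dbp1 against Ded1 they were cell wall genes in mRNA and Gcn4 targets in footprints. For 21 of the 60 lists, most of them in 2xDbp1 against Dbp1, the replicates of 1 genotype differed by more than the change of the list's mean. Leaving out 1 library of the compared genotypes, a step chosen after seeing the data, made that change over 1.5 times smaller for 36 of the 60. Among these it turned the direction of 5: respiratory chain genes in both library types of 2xDbp1 against Dbp1, Gcn4 targets and ergosterol genes in 2xDbp1 against Ded1 mRNA, and Gcn4 targets in Dbp1 against Ded1 footprints. General stress genes were not among the 36 in any comparison.

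Both DBP1 genotypes were set against the same Ded1 libraries, and their changes went together across genes. Over all genes but the helicases, 75.6% had the same sign in both comparisons in mRNA and 75.5% in footprints, against 66.7% in each when unchanged genotypes were simulated. Across genes, which are not independent replicates, the 2 sets of log2 fold changes correlated at 0.685 in mRNA and 0.753 in footprints, where the simulations, with shared controls, gave 0.503 and 0.499. The covariances were 0.0529 and 0.0543, against 0.012 and 0.0101 simulated, a difference of 0.0409 and 0.0442. With a different Ded1 library for each comparison, the correlations were 0.326 and 0.449 in mRNA and 0.296 and 0.626 in footprints. These pairs of comparisons share no library, so the simulated values, which hold for shared controls, are no baseline for them. Independent noise alone would favour no correlation there, which was not simulated. Each such control was 1 library, which adds noise. The correlations nevertheless stayed positive without a shared library. The excess is what remains beyond the simulated share of the shared controls. That simulation gave every genotype the same spread for a gene and drew independent noise. Whether the real shared controls add more than the simulated ones was not tested. Translational efficiency correlated at 0.547, against 0.5 simulated, and at 0.147 and 0.081 with a different Ded1 library for each. MBB1 passed as higher in both comparisons in mRNA and MET2 as lower in both in footprints, each time against the same Ded1 libraries.

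**Figure D3:**
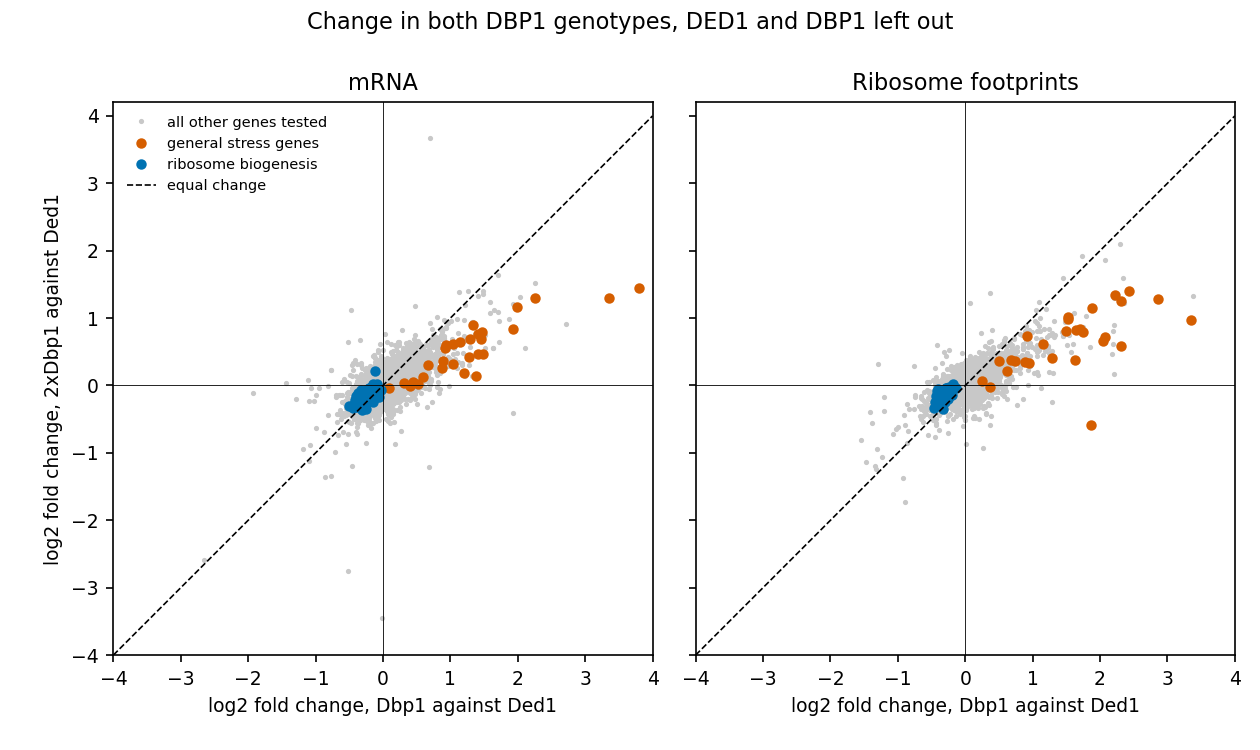
Log2 fold change against Ded1 in 2xDbp1 (vertical axis) and in Dbp1 (horizontal axis), for mRNA (left) and footprints (right); each point is a gene, with general stress genes in orange and ribosome biogenesis genes in blue. General stress genes had medians of +1.18 in Dbp1 and +0.47 in 2xDbp1 in mRNA and mostly lie under the dashed line of equal change.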

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

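The crossed pairing, leaving RPP1 off the ribosomal protein list, and the change of list means without each library were chosen after seeing the data. Without RPP1 every list count was the same. With an estimated inter-gene correlation, lists called fell to 0 in all 9 tests. They fell from 8, 12 and 12 in mRNA, 10, 9 and 9 in footprints, and 2, 2 and 3 in translational efficiency. The order is Dbp1 against Ded1, 2xDbp1 against Ded1 and 2xDbp1 against Dbp1. That setting also lowers camera's degrees of freedom to those of the residuals, 3 in mRNA and footprints and 6 in translational efficiency. How much each part of the setting contributed was not tested. With the 2 compared genotypes alone, a fit on fewer libraries, mRNA counts went from 79 to 8 for Dbp1 against Ded1 and from 4 to 26 for 2xDbp1 against Ded1, and footprint counts from 160 to 45, from 3 to 12 and from 0 to 1. No filter gave 96 footprint calls for Dbp1 against Ded1 and 1 in translational efficiency for 2xDbp1 against Dbp1. A minimum mean of 20 gave 10, and rescaling 8, in mRNA for 2xDbp1 against Ded1, and a pseudocount of 5 gave 2 for 2xDbp1 against Dbp1. The cause was not tested. Leaving out each library, where a lone library is assumed to vary like the other groups, gave 2 to 208 and 22 to 245 calls for Dbp1 against Ded1 in mRNA and footprints, 3 to 27 and 2 to 22 for 2xDbp1 against Ded1, and 1 to 6 and 0 to 1 for 2xDbp1 against Dbp1. In translational efficiency it gave 2, 2 and 0 throughout.

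Across genotypes the replicate numbers were not taken as pairs, since not every correlation of deviations was over 0.1. Those with Ded1 were over it, and those of 2xDbp1 with Dbp1 were not. For 2xDbp1 with Dbp1, 2xDbp1 with Ded1 and Dbp1 with Ded1 these were -0.107, 0.325 and 0.166 in mRNA and -0.071, 0.355 and 0.191 in footprints. The replicate block, in which MET2 footprints in 2xDbp1 against Ded1 did not pass (adjusted p = 0.0638), gave 116, 7 and 4 calls in mRNA, 143, 5 and 0 in footprints, and 2, 2 and 0 in translational efficiency. With the block, 9, 13 and 11 lists passed in mRNA and 10, 11 and 10 in footprints. Of the 67 list calls it kept 66. The crossed pairing for 2xDbp1 against Dbp1 in mRNA gave 2 calls, against 1. The pairs of mRNA and footprint libraries gave 3, 4 and 0 calls in translational efficiency and changed no other call than those given with the results.

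With different Ded1 libraries for each comparison, correlations were 0.326 and 0.449 in mRNA, 0.296 and 0.626 in footprints, and 0.147 and 0.081 in translational efficiency. The direction turned in 3 cases: the Hsf1-dependent chaperone median in mRNA for Dbp1 against Ded1 (-0.004 after rescaling), and DED1 translational efficiency for 2xDbp1 against Dbp1 (-0.044 without 2xDbp1 footprint replicate 1, -0.125 without Dbp1 footprint replicate 1, 0.347 at most, 0.111 in the main fit), where few DED1 reads remain. Among 48 named calls, rescaling ended 1, no filter 12, a pseudocount of 5 ended 1, the 2 compared genotypes alone 26 and the replicate block 2 (with 7 gained), and over all left-out libraries 134 of 312 calls were lost. These alternatives were recomputed for 155 named values. Another 152 values that the rule would name, none past the threshold and all in lists that were not called, were set aside after a first run and are not printed, and 51 of their alternatives turned direction. Simulated 1.5-fold changes were recovered in 41.8% of cases in translational efficiency, 68.7% in mRNA and 85.1% in footprints.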

Other observations

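Among the tests below, those on glucose-repressed genes and on the genes near TRP1 were set before their results were seen, and the others were chosen after, as was the list of sulfate assimilation and methionine genes. In that list, 4 of 18 members fell in Dbp1 mRNA and 7 of 17 in footprints, with medians of -0.50 (adjusted p = 3.38e-10 over 18 tests, and adjusted p = 0.257 with an estimated correlation) and -0.86 (adjusted p = 1.99e-10, and adjusted p = 0.257 with an estimated correlation). In 2xDbp1 the medians were -0.59 in mRNA (0 of 18 past the threshold, adjusted p = 1.34e-12, and adjusted p = 0.257 with an estimated correlation) and -0.68 in footprints (1 of 17, adjusted p = 4.48e-15, and adjusted p = 0.257 with an estimated correlation). In translational efficiency the Dbp1 median was -0.23 (0 of 17 past the threshold, adjusted p = 0.00358, and adjusted p = 0.493 with an estimated correlation), while the list did not pass in 2xDbp1 against Ded1 (median -0.14, adjusted p = 0.132) or between the DBP1 genotypes (median +0.12, adjusted p = 0.396). Between the DBP1 genotypes the mRNA and footprint medians were -0.05 and +0.145 (adjusted p = 0.952 and 0.221). Since the list was drawn up from genes seen to be low, its direction is no independent evidence.

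Further lists did not pass in Dbp1 against Ded1 mRNA. Meiotic and sporulation genes had 2 measured members (median -0.05, adjusted p = 0.683), and haploid-specific and mating genes 4 (median +0.17, adjusted p = 0.451). Medians were -0.14 for cyclins (adjusted p = 0.199), -0.10 for histones (adjusted p = 0.199), +0.06 for the proteasome (adjusted p = 0.552), +0.16 for the iron regulon (adjusted p = 0.683), +0.22 for amino acid genes under Gcn4 (adjusted p = 0.0917), and +0.11 for genes with known upstream open reading frames (adjusted p = 0.365). Strain marker genes had a median of -0.02 and a mean of +0.02 there (adjusted p = 0.687). The 7 glucose-repressed genes with a mean of at least 5 RPKM, tested as a list, had medians of +0.39 in Dbp1 (adjusted p = 0.045) and +0.45 in 2xDbp1 (adjusted p = 0.0324), with 0 past the threshold and adjusted p = 0.726 with an estimated correlation for each. Strain marker genes differed in 2xDbp1 against Ded1, where TRP1 alone passed: their median was -0.24 (adjusted p = 0.00801, and adjusted p = 0.626 with an estimated correlation).

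General stress genes were highest in Dbp1, lower in 2xDbp1 and lowest in Ded1, in both library types. Since same-numbered mRNA and footprint libraries deviated together, the library types are not independent evidence of this order. Scaling of the libraries is argued against, since the list's median in Dbp1 was +1.14 after rescaling, against +1.18. Cultures running low in glucose could raise such genes. Over 13 glucose-repressed genes the median was 0.446 in 2xDbp1, where stress genes were lower than in Dbp1. In Dbp1 it was 0.226 (95% bootstrap interval 0.048 to 0.463), under the bound of 0.5 set beforehand. The bootstrap drew genes, not libraries, so its intervals do not measure the spread between libraries. A second condition was added after that result was seen, because 6 of the 13 genes have means under 5 RPKM: over the other 7 the median was 0.391 (0.169 to 1.057), so this explanation stays open. For chance differences between cultures the test was void, since the 6.7% of arrangements that leave no overlap is the lowest share 2 libraries per genotype can give, so that explanation is neither excluded nor supported.

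TRP1 mRNA fell in 2xDbp1 while YDR008C, an unnamed gene that overlaps it and was chosen after its values were seen, was at 16.2 ± 0.721 RPKM against 0.404 ± 0.572 in Ded1 (adjusted p = 0.051). TRP1 footprints were near 0 in every genotype, 0.901 ± 0.047 RPKM in Ded1, 1.36 ± 0.438 in Dbp1 and 0.948 ± 0.251 in 2xDbp1. Reads moving between the gene models would keep their sum, but it was 0.289 times that of Ded1, with YDR008C, absent from the reference, given the length of TRP1. A lower tryptophan pathway is argued against by TRP2 to TRP5, whose median was -0.051. A strain difference at this locus, such as an inserted construct, may account for the pattern, but no sequence was there to test it. Of the 4 nearest genes that do not overlap TRP1, 0 moved by more than 0.5. Any change confined to TRP1 would leave them so, so this cannot tell a strain difference from another cause.

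Translational efficiency changes followed coding length across 4742 genes. Spearman correlations were -0.184 for Dbp1 against Ded1, 0.173 for 2xDbp1 against Ded1 and 0.365 for 2xDbp1 against Dbp1. In 2xDbp1 against Dbp1 the median change was -0.058 for genes up to 676 nt and 0.111 for genes from 2097 nt. For 2xDbp1 against Ded1 the correlation was -0.224 in mRNA and -0.072 in footprints. That trend therefore lay mainly in mRNA and does not show more footprints on long genes. For 2xDbp1 against Dbp1 these correlations were -0.191 and 0.185, and for Dbp1 against Ded1 -0.06 and -0.179. In translational efficiency, the difference between the 2 Ded1 replicates had a correlation of -0.303, beyond that of 2xDbp1 against Ded1. Dbp1 and 2xDbp1 replicates gave -0.11 and 0.013. Length bias that varies between libraries is therefore a candidate explanation for 2xDbp1 against Ded1. The larger value between the DBP1 genotypes exceeds what any replicates gave, and a genotype effect on long or short genes stays open and was not tested.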
